A study of Mus musculus with 9 samples.

How the data were processed

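Total RNA of 9 mouse bone marrow cell samples, 3 each with NUP98-CDX1, NUP98-CDX4 or EGFP, was hybridized to single-colour Illumina bead arrays of 45281 probes. Per the labels, the cells of 5-FU-treated mice were transfected and grown in medium with 2% serum, stem cell factor and IL-6, RNA was extracted with Trizol, cleaned on columns with DNase and checked on a Bioanalyser, and biotin-labelled cRNA was made with an Ambion kit. The intensity values used here are probe signals that the authors exported from GenomeStudio without normalization, and the GenomeStudio version is not given in the sources used here. The detection p-value of each probe and array is used as deposited by the authors, from GenomeStudio's comparison with negative control beads. The authors also deposited processed intensities of unstated normalization, which served only as an alternative. Their column medians ran from 84.28 to 85.81, so they are not plainly quantile normalized, and each column correlated most with its own raw column (Spearman at least 0.991, against at most 0.953 with any other).

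Signals were background corrected and quantile normalized with neqc of limma 3.58.1 (negative controls inferred from the detection p-values, offset 16) and put on the log2 scale, in R 4.3.3 with the data.table package, version 1.17.8. Probes with a detection p under 0.05 on at least 3 of 9 arrays were kept, 19472 in all, while 21684 probes were detected on no array. Symbols came from the platform annotation (34885 probes with 1 symbol, 18 with several, 10378 with none), and 34807 probes matched the RefSeq gene table by Entrez number, which changed 0 symbols. The brightest probe by mean over all arrays stood for a gene. This gave 13160 features, 10018 named genes and 3142 probes without a symbol, which were tested but are only counted. For 67 of the 178 genes named by the rule below another filtered probe was tested, and in 327 pairs of probe and comparison 0 were called in opposite directions. Another probe did not pass and moved under 0.5 times as far, or the other way, for Bcl2, Pmaip1 and Ppm1e in NUP98-CDX1, for Acta2, Angpt1, Ctnnal1, Kmt2a, Mllt3, Pbx4, Ppm1e and Tcf4 in NUP98-CDX4, and for Stfa2 between the fusions. A group where a probe was detected on 0 of 3 arrays gives only a bound, computed with each of its arrays raised to that array's lowest detected signal and written as at least so many fold, and list medians were repeated with such genes at their bound. Where it was detected on 1 of 3, the undetected arrays were raised in the same way for the fold of the named gene.

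One limma linear model with a mean per group was fitted to the 9 arrays with empirical Bayes variances, and p-values were adjusted by Benjamini and Hochberg over all features, with 0.05 as the threshold. The comparisons were each fusion with EGFP, the fusions with each other, and the mean of both fusions with EGFP. Counts of 31 gene lists, fixed before the data were examined together with the alternatives, the design and the naming rule, are given over all genes and adjusted over the list alone. Each list with at least 3 measured genes was tested with camera at the preset correlation of 0.01, again with an estimated correlation, and with fry. The fry test asks whether the genes of a list move on balance one way, without comparing them with other genes, and called 10, 16 and 6 lists in the order NUP98-CDX1, NUP98-CDX4 and NUP98-CDX4 against NUP98-CDX1, and 14 for the mean.

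Genes were named by rule. In each comparison with EGFP the fused genes were named, and the 10 largest rises and 10 largest falls among genes under the threshold whose 3 arrays of 1 group all lay above the other 3 and were all detected in the higher group, passing over clone names. From each list up to 4 members with the smallest adjusted p were named, and every measured Hoxa, Hoxb, Meis and Pbx gene. Between the fusions the rule took 5 and 5, and for shared changes 5 and 5 by the smaller change. Eligible were 73 rises and 48 falls for NUP98-CDX1, 265 and 330 for NUP98-CDX4, and 4 and 14 between the fusions, where chance gives 10% of genes groups of 3 that do not overlap. A further few members of lists are named to complete a count, and were chosen after their values were seen. The text leaves out some of the named genes that did not pass.

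The array sets were found in the data, from the signals of undetected probes, and the labels name no batch. Array set was added to the model as a block, and each set was fitted alone. Simulated independent noise with each gene's residual SD and no effect gave the correlation and covariance that shared EGFP arrays produce, in 100 draws. The pipeline was tested on simulated data with 200 of 13160 features changed. A change of 1 on the log2 scale was recovered for 22% of them in NUP98-CDX1 and 33% in NUP98-CDX4, and for 78% and 80.5% with array set as a block. A change of 2 was recovered for 86.5% and 91.5%, and for 97.5% and 99% with the block, and the sign was right in all recovered. The false calls numbered 0 to 13, and camera called the 1 shifted list and 0 of 30 unshifted ones. The simulated lists had noise independent between genes and no array sets. They do not show how often camera calls unshifted lists whose genes correlate.

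Alternatives tried were no background correction, an offset of 50, median scaling, the authors' processed values, no filter, a stricter detection filter, the mean of probes or every probe, a trended and robust fit, array weights, a replicate block, the groups compared alone, an adjusted p under 0.01, a change of at least 2-fold and leaving out each array. Chosen after seeing the data were array set as a block, each set alone, and array set and Xist as blocks. Median and mean intensities described the arrays, and the day numbers in the column names and sex-linked genes were used to weigh explanations. Intensities of probes without a gene name were not analysed here beyond their count. The precision is limited by the number of arrays.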

Results

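Gene expression was measured on 9 single-colour Illumina mouse bead arrays, 1 per RNA sample. The cells came from the bone marrow of C57/B6 mice aged 6 to 8 weeks that had received 5-FU, a drug that kills dividing cells. They carried NUP98-CDX1, NUP98-CDX4 or, as control, the green fluorescent protein EGFP, with n = 3 arrays per group, and grew with stem cell factor and IL-6. Each fusion joins part of the nuclear pore protein NUP98 to a caudal-type homeobox transcription factor, CDX1 or CDX4. Each array detected 17257 to 19300 of its 45281 probes (38.1% to 42.6%), at a mean signal of 400.6 to 754.3 intensity units. For 10018 genes with a probe detected on at least 3 arrays, values are log2 intensities given as mean ± SD with n = 3 arrays per group. The number of arrays limits the precision. The column names hold day numbers of unstated meaning, 21 for EGFP, 28 for NUP98-CDX1 and 17 or 20 for NUP98-CDX4. No day number is shared by 2 groups, so a difference between groups may also come from the day. The labels do not say whether the replicates were separate cultures or animals, so p-values measure the spread between these samples, part of which may be technical. A gene is said to rise or fall where its adjusted p was under 0.05.

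The arrays fell into 2 sets that crossed the groups. Among probes detected on no array, Spearman correlations were 0.73 to 0.77 within a brighter set, EGFP replicates 1 and 2, NUP98-CDX1 replicate 3 and NUP98-CDX4 replicates 1 and 3. They were 0.43 to 0.46 within the dimmer set of the other 4 arrays and 0.32 to 0.38 between the sets. The sets lay apart on the first principal component, which held 45.5% of the variance, and the groups on the second, with 31.4%. Values are therefore also given with array set as a block and within each set. Within a set, at least 1 group has a single array. EGFP and NUP98-CDX4 hold the same mix of sets, so the block leaves their fold change as it is and alters only its error.

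Xist, the RNA that silences an X chromosome in female cells, read 11.33 to 11.87 on NUP98-CDX1 replicate 1 and NUP98-CDX4 replicates 1 and 2. The brightest probes of the Y-linked genes Eif2s3y and Kdm5d were not detected on these 3 arrays. A second Eif2s3y probe was detected on 1 of them (at 5.345) and a probe of the Y-linked Uty on all 3 (5.283 to 5.502), near the lowest detected signals of 5.255 to 5.41. On the other 6 arrays, all 3 of EGFP among them, Xist read 4.47 to 4.58 and was not detected, and Eif2s3y read 9.88 to 10.45. Of 4 sex-linked genes measured, none passed in any comparison, also when adjusted over the list alone. The camera adjusted p of this list was 0.46 for NUP98-CDX1, 0.48 for NUP98-CDX4 and 0.87 between the fusions.

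The fused genes were examined first, as a check of the labels. The brighter Cdx1 probe was detected on 5 of 9 arrays and read 5.54 ± 0.68 in EGFP, 5.21 ± 0.56 in NUP98-CDX1 and 5.50 ± 0.67 in NUP98-CDX4. The other Cdx1 probe was detected on 0 arrays and the Cdx4 probe on 1, an EGFP array. Nup98 read 8.44 ± 0.28, 8.82 ± 0.43 and 8.61 ± 0.30 in the same order. No fused gene passed, the lowest adjusted p of any of their probes, and of Cdx2, being 0.727 without a detection filter. Whether the probes lie inside the constructs, or match their species, is not given in the sources used here, so these values check nothing about which cells carried which fusion.

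The comparison of NUP98-CDX1 with EGFP asks which transcripts differ in marrow cells that carry this fusion. Cells with NUP98-CDX1 held more RNA of several Hoxa genes and of the Hox partner Pbx3, and of a group of genes that were low or undetected in EGFP cells, among them Eya1 and Hpgd. They held less RNA of 8 of 25 late neutrophil, 5 of 25 macrophage and 4 of 12 mast cell genes, and the calls of these lists were lost with an estimated correlation. Of 10018 genes, 123 passed, 73 higher and 50 lower, and 109 of them differed at least 2-fold. With array set as a block 619 passed, 323 higher and 296 lower. All 123 kept their call in the block and their sign in both sets, although they were selected on these same arrays. Of 3142 features without a gene name, 14 passed.

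In the Hoxa cluster, homeobox genes of positional identity whose members sustain blood progenitors, 4 of 8 measured genes rose, none fell and 4 did not pass. Adjusted over the list alone the count was also 4. Hoxa5 rose from 7.39 ± 0.40 to 9.74 ± 0.25, 5.10-fold (adjusted p = 0.00162, 0.00018 with array set as a block and 4.15e-05 to 0.055 over all alternatives). Hoxa9, a gene that keeps progenitors immature, rose 4.38-fold (adjusted p = 0.0249) and Hoxa7 3.29-fold (adjusted p = 0.00585). Hoxa2, undetected in EGFP, rose at least 1.82-fold (adjusted p = 0.0499). Hoxa4 and Hoxa13 did not pass, and Hoxa3 and Hoxa10 were detected in neither group. The list median was 0.82, or 0.73 with undetected genes at their bound. It was 0.71 with array set as a block, 0.64 within the brighter set and 0.84 within the dimmer set. The median was 1.385, 1.383 and 1.387 without NUP98-CDX4 replicates 1, 2 and 3. Hoxa3 and Hoxa10 pass the detection filter only through the 3 NUP98-CDX4 arrays, so they leave the list in these fits and the median is of fewer genes. With all arrays the camera adjusted p was 8.7e-07, against 0.061 with an estimated correlation.

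Among 8 Hox cofactors of the TALE homeodomain class, Pbx3 rose 3.37-fold (adjusted p = 0.0132), the other 7 did not pass, and 3 rose with adjustment over the list alone. Meis1, the cofactor that binds DNA with Hoxa9, read 9.82 ± 0.08 and 10.80 ± 0.40 and did not pass (adjusted p = 0.0571), but passed with array set as a block (adjusted p = 0.0136, 0.00318 to 0.341 over all alternatives). The list as a whole did not pass (camera adjusted p = 0.061), but did in 11 of 24 other settings, array set as a block among them (0.041, and 0.015 to 0.364 over all alternatives). Of 19 genes tied to HOX and NUP98 fusion leukaemia, 3 rose, 16 did not pass and none fell, with 5 rising over the list alone (camera adjusted p = 0.099). The 3 were Eya1, a transcriptional coactivator with phosphatase activity, from 4.91 ± 0.40 to 8.38 ± 0.22 (7.85-fold with undetected arrays raised to their lowest detected signal, adjusted p = 0.000195, detected on 1 of 3 EGFP arrays), the survival gene Bcl2 (1.86-fold) and the transcription factor Mef2c (2.34-fold). Other probes of Bcl2 did not pass. The list of 21 stem and progenitor cell genes passed as higher (camera adjusted p = 0.00021, 0.061 with an estimated correlation) although none passed singly and 8 rose over the list alone. Their median was 0.37, 0.40 in the block, 0.40 within the brighter set and 0.36 within the dimmer set. Mllt3, a regulator of stem cell self-renewal, came nearest after Meis1 (2.22-fold, adjusted p = 0.0625).

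The largest rise was in Vldlr, a lipoprotein receptor, from 5.71 ± 0.47 to 9.41 ± 0.29, 13.0-fold (adjusted p = 0.00246), detected on 2 of 3 EGFP arrays. Dlk1, a membrane protein of the Notch ligand family that marks immature cells, rose 10.6-fold (adjusted p = 0.00933), with detection on 2 of 3 EGFP arrays. Adgrl4, an adhesion receptor of endothelium, rose 9.20-fold, and Igfbp7, a secreted binding protein of growth factors, 7.24-fold. Hpgd, the enzyme that inactivates prostaglandins, rose from undetected to 8.04 ± 0.21, at least 6.38-fold (adjusted p = 0.000331). The phosphatase gene Ppm1e, also undetected in EGFP, rose at least 4.85-fold, though 2 other probes of it did not pass. Gpc3, a glypican of the cell surface, rose 7.74-fold (adjusted p = 0.0104), the actin-associated Synpo 6.87-fold, and H2-Ob, a chain that limits peptide loading on MHC class II, 6.21-fold, the last 2 detected on 1 of 3 EGFP arrays with the others raised.

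Of 25 late neutrophil genes, 8 fell, none rose and 17 did not pass, with 14 falling over the list alone. Stfa2, a cysteine protease inhibitor, fell from 11.74 ± 0.03 to 7.66 ± 0.23, 16.9-fold (adjusted p = 0.000195). Camp, an antimicrobial peptide, fell 7.51-fold (adjusted p = 0.000594) and lactoferrin (Ltf) 6.60-fold (adjusted p = 0.0398). Stfa2l1 fell at least 4.92-fold and the gelatinase Mmp9 at least 2.48-fold, both undetected with the fusion. Outside the list, the related inhibitor genes Csta3 and Cstdc5 fell 5.63-fold and 9.61-fold. These stefin genes are near copies of each other, so a probe may read more than 1 of them. The list median was -1.12, -1.20 in the block, -1.30 within the brighter set and -0.89 within the dimmer set. The camera adjusted p was 5.6e-18, and 0.061 with an estimated correlation.

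Of 25 monocyte and macrophage genes, 5 fell, 1 rose and 19 did not pass, with 11 falling and 1 rising over the list alone. Adgre1, the macrophage marker F4/80, fell 2.46-fold from 10.14 ± 0.13 to 8.84 ± 0.03 (adjusted p = 0.0281). Ms4a7 fell 2.72-fold, the protease gene Ctss 2.26-fold and the transcription factor Klf4, undetected with the fusion, at least 1.60-fold. Cd14, a receptor for bacterial lipid, went the other way, 1.81-fold higher (adjusted p = 0.0314). The median was -0.73, or -0.65 at the bounds, -0.78 in the block, -0.80 within the brighter set and -0.94 within the dimmer set (camera adjusted p = 9.6e-11, 0.13 with an estimated correlation).

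Of 12 mast cell genes, 4 fell and 8 did not pass, with 6 falling over the list alone, and the 4 were all secretory proteases. Cma2 fell from 10.17 ± 0.32 to 6.18 ± 0.50, 15.8-fold (adjusted p = 0.000195), Mcpt4 12.3-fold, Cma1 7.97-fold, and Tpsb2, undetected with the fusion, at least 8.42-fold. Cpa3, a protease of the same granules, did not pass (11.79 ± 0.28 and 11.68 ± 0.04, adjusted p = 0.866). The median was -0.44, -0.48 in the block, -0.26 within the brighter set, -0.61 within the dimmer set and -0.072 without EGFP replicate 2 (camera adjusted p = 2.6e-06, 0.13 with an estimated correlation).

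Of 31 type I interferon response genes, 2 fell and 29 did not pass, with 9 falling over the list alone. Ifi204, a sensor of DNA, fell 3.93-fold (adjusted p = 0.00124) and the antiviral gene Mx1 2.45-fold (adjusted p = 0.0468). The median was -0.56, -0.73 in the block, -0.56 within the brighter set and -0.62 within the dimmer set (camera adjusted p = 8.6e-12, 0.22 with an estimated correlation). The list of 22 glycolysis and hypoxia genes passed as higher (camera adjusted p = 2.8e-05, 0.099 with an estimated correlation), with 2 passing, 20 not, and 4 over the list alone. The 2 were Vegfa, a growth factor induced by low oxygen (2.71-fold, adjusted p = 0.019), and Ankrd37 (2.75-fold, adjusted p = 0.0171). Their median was 0.34, 0.30 in the block, 0.31 within the brighter set and 0.34 within the dimmer set.

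Another 4 lists passed as higher in NUP98-CDX1 with few or no members passing. Of 22 NF-kB and inflammatory genes, the chemokine Ccl3 rose 5.11-fold (adjusted p = 0.00311), the chemokine Ccl2 fell 2.53-fold and 20 did not pass, with 5 rising and 2 falling over the list alone. This list had a median of 0.43 (camera adjusted p = 0.015, 0.54 with an estimated correlation), but 0.20 and camera adjusted p = 0.069 with array set as a block (0.00254 to 0.135 over all alternatives), 0.28 within the brighter set and 0.40 within the dimmer set. Its call was lost without EGFP replicate 2 (adjusted p = 0.0694), NUP98-CDX1 replicate 1 (0.111) or NUP98-CDX1 replicate 2 (0.0709), and its median was 0.239 without NUP98-CDX1 replicate 1 and 0.656 without NUP98-CDX1 replicate 3. Of 20 immediate early and heat shock genes none passed, also over the list alone, and Egr1 read 10.30 ± 2.23. Their median of 0.38 (camera adjusted p = 0.021, 0.49 with an estimated correlation) was 0.18 in the block (camera adjusted p = 0.16, and 0.00102 to 0.434 over all alternatives), 0.12 within the brighter set and 0.40 within the dimmer set. This call was lost without NUP98-CDX1 replicate 1 (adjusted p = 0.208, median 0.182) or EGFP replicate 2 (0.0694), the median being 0.628 without NUP98-CDX1 replicate 3, and the list's centred mean, adjusted for array set, was 0.64 on NUP98-CDX1 replicate 1, -0.11 on replicate 2 and 0.02 on replicate 3. Of 18 cholesterol genes none passed either way of adjusting (median 0.20, 0.18 in the block, 0.15 and 0.17 within the brighter and the dimmer set). Their camera adjusted p was 0.033, 0.13 with an estimated correlation, and 0.0694, 0.117 and 0.179 without EGFP replicate 2, EGFP replicate 3 and NUP98-CDX1 replicate 3. Of 22 polycomb and trithorax genes none passed either way (median 0.20, 0.14 in the block, 0.15 and 0.14 within the sets). Their camera adjusted p was 0.009, 0.12 with an estimated correlation.

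The other 19 lists apart from the sex-linked genes did not pass in NUP98-CDX1, 2 of them, the cofactors and the leukaemia genes, being given above. None of 4 Hoxb genes (camera adjusted p = 0.72), 4 Hoxc and Hoxd genes (0.68), 4 T and NK cell genes (0.98), 7 stromal and endothelial genes (0.28), 5 intestinal genes tied to CDX factors (0.97) or 22 ribosome and Myc genes (0.98) passed singly or over the list alone. The same held for 30 genes of G1/S and replication (0.41), 25 of G2/M (0.19) and 23 of the amino acid response (0.28). No gene passed among 11 basophil and eosinophil genes (0.099), 14 megakaryocyte genes (0.35), 8 B cell genes (0.27), 11 dendritic cell genes (0.42) and 4 Wnt genes (0.14). Over the list alone these held 3 falling, 2 rising and 1 falling, 2 rising, 2 rising and 1 falling, and 1 rising gene. Of 15 primary granule genes only Nkg7 rose, a granule membrane protein (2.36-fold, camera adjusted p = 0.46 for the list), of 17 erythroid genes only the repressor Gfi1b (2.02-fold, 0.27) and of 22 p53 and cell cycle inhibitor genes only Pmaip1 (2.10-fold, 0.27). Over the list alone 1, 3 and 1 rose. Another probe of Pmaip1 did not pass. For the T and NK cell, ribosome and intestinal lists the median, the mean and the test differed in sign.

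Differences were tested with limma and each list with camera at its preset correlation, and all 11 list calls were lost with an estimated correlation. Without EGFP replicates 1, 2 or 3 the count of 123 was 38, 24 or 74, without NUP98-CDX1 replicates 1 or 2 it was 41 or 32, and of the 41 named genes called only Hpgd, Stfa2 and Tpsb2 held in every setting tried.

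The comparison of NUP98-CDX4 with EGFP asks the same for the other fusion. NUP98-CDX4 cells held more RNA of 6 of 8 Hoxa genes and of Meis1, and less RNA of many late neutrophil, mast cell, macrophage and interferon response genes. Here 611 genes passed, 274 higher and 337 lower (6.10%), and 431 differed at least 2-fold. The block on array set gave 1835, 977 higher and 858 lower. All 611 kept their call in the block and their sign within both sets, again selected on these arrays. Of the features without a gene name 95 passed.

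In the Hoxa cluster 6 of 8 genes rose and 2, Hoxa4 and Hoxa13, did not pass, with 6 also over the list alone. Hoxa5 rose to 10.58 ± 0.16, 9.13-fold (adjusted p = 0.000141, 6.16e-06 with array set as a block and 1.21e-06 to 0.0293 over all alternatives). Hoxa9 rose 7.44-fold from 7.37 ± 0.84 to 10.26 ± 0.06 (adjusted p = 0.00156) and Hoxa7 5.19-fold. Hoxa2 rose at least 3.09-fold, Hoxa10 at least 1.63-fold and Hoxa3 at least 1.57-fold, all undetected in EGFP. Hoxa3 and Hoxa10 pass the detection filter only through the NUP98-CDX4 arrays, so their place in the list is not independent of their rise. The median was 1.58, or 1.17 at the bounds, 1.49 within the brighter set and 1.74 within the dimmer set (camera adjusted p = 1.7e-10, 0.02 with an estimated correlation).

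Among 8 TALE cofactors 3 rose, also over the list alone, and 5 did not pass. They were Meis1, from 9.82 ± 0.08 to 11.60 ± 0.06 (3.43-fold, adjusted p = 0.00123), Pbx3 (2.35-fold, adjusted p = 0.0182) and Pbx4 (1.80-fold, adjusted p = 0.0484). Another probe of Pbx4 did not pass, with a log2 change of -0.115. The list median was 0.35, with 0.40 within the brighter set, 0.25 within the dimmer set, 0.606 without EGFP replicate 2 and 0.579 without NUP98-CDX4 replicate 2 (camera adjusted p = 0.018, 0.081 with an estimated correlation). Of 19 leukaemia genes 4 rose and 15 did not pass, with 5 rising and 2 falling over the list alone. Eya1 rose to 9.08 ± 0.24, 12.8-fold with undetected EGFP arrays raised (adjusted p = 2e-05), Mef2c 3.15-fold, Bcl2 2.46-fold and the transcription factor Sox4 2.07-fold. The leukaemia list had a median of 0.17, 0.16 within the brighter set and 0.33 within the dimmer set, and its camera adjusted p was 0.037, 0.35 with an estimated correlation, 0.15 in the block and 0.0117 to 0.235 over all alternatives, being lost without EGFP replicate 1 (0.0904), NUP98-CDX1 replicate 3 (0.0561) or NUP98-CDX4 replicate 2 (0.225). Its median was 0.262 without EGFP replicate 3 and 0.009, about 0, without NUP98-CDX4 replicate 2. Of 21 stem and progenitor cell genes 6 rose, 1 fell and 14 did not pass, with 8 rising and 1 falling over the list alone. Besides Meis1 these included Ctnnal1 (2.86-fold), Mllt3 (2.40-fold) and the receptor ligand Angpt1 (1.64-fold, adjusted p = 0.0393), while the surface marker Prom1 fell by 1.10 on the log2 scale. Other probes did not pass, with log2 changes of 0.131 and 0.296 for Ctnnal1, -0.103 for Mllt3 and 0.072 for Angpt1. The stem cell list median was 0.30, 0.29 within the brighter set, 0.50 within the dimmer set and 0.462 without NUP98-CDX4 replicate 2 (camera adjusted p = 0.00039, 0.045 with an estimated correlation).

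Hpgd showed the largest rise, from undetected to 10.50 ± 0.38, at least 35.3-fold (adjusted p = 5.37e-06). Dlk1 rose 20.4-fold to 9.70 ± 0.79 (adjusted p = 0.000917), Vldlr 12.6-fold and Adgrl4 9.39-fold. Il12a, a subunit of interleukin 12, rose 10.8-fold from 7.89 ± 0.32 (adjusted p = 0.000259), against 6.04-fold in NUP98-CDX1 (adjusted p = 0.00311). Ppm1e rose at least 7.30-fold (another probe did not pass), Igfbp7 6.27-fold and, with undetected EGFP arrays raised, H2-Ob 7.41-fold and Synpo 3.43-fold. Clec10a, a lectin of dendritic cells and macrophages, rose from undetected at least 2.96-fold (adjusted p = 0.000779). Gpc3 did not pass (1.80-fold, adjusted p = 0.338), nor did its difference between the fusions (adjusted p = 0.0981).

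Of 25 late neutrophil genes 18 fell, none rose and 7 did not pass, with 19 falling and 1 rising over the list alone. The inhibitor gene Stfa1 fell 75.3-fold, and Stfa2, detected on 1 of 3 arrays, by 75-fold with undetected arrays raised to their lowest detected signal (adjusted p = 5.37e-06). Lactoferrin (Ltf) fell 57.1-fold to 5.99 ± 1.12 (2 of 3 arrays, adjusted p = 0.000354), Ngp, a granule protein, 40.5-fold (2 of 3 arrays), and S100a9, a calcium-binding protein of neutrophils, 32.6-fold to 8.95 ± 0.87. Camp fell 24-fold with undetected arrays raised (1 of 3 arrays, adjusted p = 1.31e-05). Outside the list Cstdc4 fell 51.9-fold (2 of 3 arrays) and Cstdc5, undetected with the fusion, at least 37.8-fold. The median was -1.96, with -2.04 within the brighter set and -1.68 within the dimmer set (camera adjusted p = 6.5e-28, 0.02 with an estimated correlation). Of 15 primary granule and early myeloid genes 4 fell, Nkg7 rose (2.55-fold) and 10 did not pass, with 8 falling and 1 rising over the list alone. The transcription factor Cebpe fell 4.55-fold (adjusted p = 0.00133), the lectin Fcnb 6.23-fold (2 of 3 arrays) and the elastase Elane 3.07-fold. The primary granule median was -0.44, -0.31 within the brighter set, -0.59 within the dimmer set and -0.289 without NUP98-CDX4 replicate 2 (camera adjusted p = 0.00085, 0.048 with an estimated correlation).

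Of 25 macrophage genes 15 fell and 10 did not pass, with 20 falling over the list alone. Ms4a7 fell 5.70-fold from 10.94 ± 0.22 to 8.43 ± 0.59 (adjusted p = 0.00123), Adgre1 4.18-fold (adjusted p = 0.00104) and the growth factor receptor Csf1r 2.40-fold (adjusted p = 0.0039). The macrophage median was -1.27, -1.38 within the brighter set and -1.35 within the dimmer set (camera adjusted p = 5.6e-18, 0.045 with an estimated correlation). Of 12 mast cell genes 8 fell and 4 did not pass, with 9 falling over the list alone. Cma2 fell at least 28.2-fold, Mcpt4 at least 16.4-fold, Cma1 at least 11.8-fold and Tpsb2 at least 8.11-fold, all undetected with the fusion. Cpa3 fell 8.33-fold to 8.73 ± 0.41 (adjusted p = 0.000204). The mast cell median was -1.86, -1.65 within the brighter set, -2.24 within the dimmer set and -1.207 without EGFP replicate 3 (camera adjusted p = 1.4e-18, 0.028 with an estimated correlation). Of 11 basophil and eosinophil genes 3 fell and 8 did not pass, with 7 falling over the list alone. They were the granule genes Prg2 (10.1-fold) and Prg3 (4.96-fold with undetected arrays raised, 1 of 3 arrays) and the receptor Cd200r3 (4.76-fold). The basophil median was -0.92, -1.12 within the brighter set, -0.52 within the dimmer set and -1.484 without EGFP replicate 3 (camera adjusted p = 1e-05, 0.061 with an estimated correlation).

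Of 31 interferon response genes 23 fell and 8 did not pass, with 29 falling over the list alone. Mx1 fell 7.81-fold from 8.29 ± 0.14 to 5.32 ± 0.43 (2 of 3 arrays, adjusted p = 0.000319), Oasl1, a gene of the oligoadenylate synthetase family, 7.31-fold, Ifi27l2a 6.02-fold and Ifi204 4.27-fold (1 of 3 arrays, the others raised). The median was -1.90, -2.06 within the brighter set and -1.47 within the dimmer set (camera adjusted p = 1.1e-34, 0.045 with an estimated correlation). Of 22 glycolysis and hypoxia genes 4 rose and 18 did not pass, with 9 rising over the list alone. These were Ankrd37 (4.89-fold), Vegfa (3.00-fold), the glycolytic Aldoc (2.98-fold) and the oxygen sensor Egln3 (2.94-fold). The glycolysis median was 0.47, 0.45 within the brighter set and 0.53 within the dimmer set (camera adjusted p = 6.7e-08, 0.036 with an estimated correlation).

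A further 4 lists passed in NUP98-CDX4 with at most 3 members passing. Of 22 polycomb and trithorax genes 3 rose and 19 did not pass, with 4 rising over the list alone. Phc1 (1.96-fold), Cbx7 (1.72-fold) and Kmt2a, the trithorax methyltransferase (1.52-fold), were the 3. Another probe of Kmt2a did not pass. The polycomb median was 0.24, 0.14 within the brighter set and 0.25 within the dimmer set (camera adjusted p = 0.0028, 0.048 with an estimated correlation). Of 18 cholesterol genes none passed either way of adjusting (median 0.32, 0.26 and 0.29 within the brighter and the dimmer set, camera adjusted p = 0.0079, 0.055 with an estimated correlation). None of 4 Wnt genes passed, with 2 rising over the list alone (median 0.48, or 0.45 at the bounds, 0.50 and 0.48 within the sets, 0.747 without NUP98-CDX4 replicate 3, camera adjusted p = 0.011, 0.081 with an estimated correlation). The Wnt call was lost with array set and Xist as blocks, and also with no detection filter. Of 23 amino acid response genes 2 fell, the cystine transporter Slc7a11 (3.36-fold, 2 of 3 arrays) and the transcription factor Cebpb (1.86-fold), and 21 did not pass, with 3 falling over the list alone. Their median was -0.12, -0.07 and -0.24 within the sets (camera adjusted p = 0.014, 0.35 with an estimated correlation and 0.103 without NUP98-CDX4 replicate 2). It was -0.204 and -0.183 without EGFP replicates 1 and 3, and -0.224 and -0.185 without NUP98-CDX4 replicates 1 and 3.

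The other lists did not pass in NUP98-CDX4. None of 4 Hoxb genes (camera adjusted p = 0.60), 4 Hoxc and Hoxd genes (0.74), 4 T and NK cell genes (0.76), 5 intestinal genes (0.40), 22 ribosome and Myc genes (0.48), 30 genes of G1/S (0.13) or 25 of G2/M (0.93) passed singly or over the list alone. Of 17 erythroid genes 2 rose, Gfi1b (2.95-fold) and carbonic anhydrase Car2 (2.50-fold), with 2 rising and 1 falling over the list alone (0.18). Of 14 megakaryocyte genes 1 rose and 2 fell, with 2 rising and 2 falling over the list alone (0.068, and under 0.05 in 10 of 24 other settings). Gp9, a platelet glycoprotein, rose 1.74-fold, and the platelet chemokine Ppbp (4.14-fold, 2 of 3 arrays) and the clotting factor F10 (2.96-fold) fell. Of 8 B cell genes 1 rose, Cd24a (3.05-fold), also over the list alone (0.31). Of 11 dendritic cell genes 2 rose, H2-DMa (3.08-fold) and the transcription factor Tcf4 (1.98-fold, another probe of which did not pass), with 2 rising and 1 falling over the list alone (0.87). Of 7 stromal genes 1 fell, the smooth muscle actin Acta2 (4.03-fold by 1 of 4 probes, the other 3 not passing), also over the list alone (0.11). Of 22 p53 and cell cycle inhibitor genes 4 rose, also over the list alone, with Cdkn2c 2.65-fold, Pmaip1 2.33-fold, Sesn1 2.34-fold and Cdkn1c 2.99-fold (0.19). Of 22 NF-kB genes Ccl3 (3.69-fold) and the inhibitor Tnfaip3 (2.29-fold) rose and the chemokine Ccl6 (3.55-fold) and Ccl2, undetected with the fusion and at least 3.14-fold lower, fell, with the same counts over the list alone (0.93). Of 20 immediate early genes 1 fell, Atf3 (2.78-fold with undetected arrays raised, 1 of 3 arrays), also over the list alone (0.56). Median, mean and test differed in sign for the dendritic cell, G2/M and NF-kB lists, and the T and NK cell median of 0.08 was -0.01 with undetected genes at their bound.

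Of the 15 lists passing camera, 9 held with an estimated correlation, and with array set as a block and an estimated correlation 0 did. Without EGFP replicates 1 or 2 the count of 611 was 346 or 277, without NUP98-CDX4 replicates 1 or 3 it was 361 or 326, and 35 of the 78 named genes called held in every setting tried. Without NUP98-CDX4 replicate 2 the calls were 163 higher and 328 lower, against 274 and 337 with all arrays.

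The comparison of NUP98-CDX4 with NUP98-CDX1 asks where the fusions differ. NUP98-CDX4 cells held more Hpgd and Hoxa10 RNA and less RNA of 2 of 12 mast cell, 4 of 25 late neutrophil and 2 of 31 interferon response genes than NUP98-CDX1 cells, and the call of the interferon list was lost with an estimated correlation. Here 18 genes passed, 4 higher and 14 lower, all at least 2-fold, and 168 with array set as a block, 38 higher and 130 lower. Hpgd read 8.04 ± 0.21 with NUP98-CDX1 and 10.50 ± 0.38 with NUP98-CDX4, 5.53-fold higher (adjusted p = 0.00732, 0.00114 in the block and 0.000186 to 0.122 over all alternatives). Hoxa10, detected on 0 NUP98-CDX1 arrays, was at least 1.71-fold higher (adjusted p = 0.0234). Clec10a, detected on 1 of 3 NUP98-CDX1 arrays, was 3.01-fold higher with the others raised (adjusted p = 0.0194) and Myadml2, a myeloid-associated gene, 2.75-fold (adjusted p = 0.0492).

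Cpa3 had the smallest adjusted p, 0.00339, at 11.68 ± 0.04 with NUP98-CDX1 and 8.73 ± 0.41 with NUP98-CDX4, 7.72-fold lower. Stfa1 was 15.2-fold lower (adjusted p = 0.0277), and with undetected arrays raised Stfa2 4.43-fold (adjusted p = 0.0126) and Camp 3.2-fold (adjusted p = 0.0234). Another probe of Stfa2 did not pass. Hsd11b1, which regenerates active glucocorticoid, was 5.75-fold lower (adjusted p = 0.0277), and Stx3, a membrane fusion protein undetected with NUP98-CDX4, at least 4.49-fold lower (adjusted p = 0.0393). Oasl1 was 4.07-fold lower (adjusted p = 0.0234) and Mx1 3.18-fold (adjusted p = 0.0486).

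Of the lists, 2 were higher and 9 lower. The Hoxa list had 1 of 8 genes passing and 5 over the list alone (median 0.76, or 0.74 at the bounds, 0.85 in the block, 0.70 and 0.77 within the brighter and the dimmer set). Its camera adjusted p was 2e-06, 0.049 with an estimated correlation and 0.083 without NUP98-CDX4 replicate 2. Hoxa10, the gene passing, and Hoxa3 pass the detection filter only through the NUP98-CDX4 arrays. Both are out of the list without NUP98-CDX4 replicate 2. Of 22 glycolysis genes none passed either way (median 0.26, 0.16 in the block, 0.12 and 0.26 within the sets, camera adjusted p = 0.0065, 0.19 with an estimated correlation). Of 12 mast cell genes 2 were lower, Cpa3 and the IgE receptor chain Fcer1a, and 9 over the list alone (median -1.24, or -0.73 at the bounds, -1.17 in the block, -1.19 and -1.28 within the sets). Their camera adjusted p was 5.3e-16, 0.049 with an estimated correlation. Of 25 late neutrophil genes 4 were lower, Stfa1, Stfa2, Camp and Anxa1, and 13 over the list alone (median -0.84, -0.76 in the block, -0.75 and -0.68 within the sets). Their camera adjusted p was 2.2e-16, 0.049 with an estimated correlation. Of 31 interferon genes 2 were lower, and 25 over the list alone (median -1.11, -1.16 in the block, -1.43 and -0.81 within the sets). Their camera adjusted p was 3.7e-30, 0.076 with an estimated correlation.

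Another 6 lists were lower with no gene passing. They were 25 macrophage genes (9 lower and 1 higher over the list alone, median -0.63, -0.48 in the block, -0.63 and -0.30 within the sets, -0.384 without NUP98-CDX4 replicate 3, camera adjusted p = 6.9e-08, 0.19 with an estimated correlation) and 15 primary granule genes (4 lower over the list alone, median -0.24, -0.29 in the block, -0.22 and -0.27 within the sets, -0.155 without NUP98-CDX1 replicate 1 and -0.151 without NUP98-CDX4 replicate 3, camera adjusted p = 6.8e-05, 0.05 with an estimated correlation). Of 11 basophil genes 4 were lower over the list alone (median -0.51, -0.62 in the block, -0.54 and -0.57 within the sets, camera adjusted p = 2e-05, 0.12 with an estimated correlation). Their median was -0.822, -0.822 and -1.131 without EGFP replicates 1, 2 and 3, -0.805 and -0.766 without NUP98-CDX1 replicates 2 and 3, and -1.092 without NUP98-CDX4 replicate 2. Of 14 megakaryocyte genes 1 was lower over the list alone (median -0.45, -0.38 in the block, -0.48 and -0.18 within the sets, camera adjusted p = 1e-04, 0.12 with an estimated correlation). Of 22 NF-kB genes 4 were lower over the list alone (median -0.45, or -0.37 at the bounds, -0.22 in the block, -0.33 and -0.001 within the sets, camera adjusted p = 8.9e-05, 0.47 with an estimated correlation). Their median was -0.162 without NUP98-CDX1 replicate 1, and -0.277 and -0.128 without NUP98-CDX4 replicates 1 and 3. Of 23 amino acid response genes 1 was lower over the list alone (median -0.09, -0.09 in the block, 0.02 and -0.27 within the sets, camera adjusted p = 0.03, 0.52 with an estimated correlation, 0.197 without NUP98-CDX1 replicate 1 and 0.451 without NUP98-CDX4 replicate 2). The amino acid median was -0.223 without NUP98-CDX1 replicate 3, and -0.177 and -0.044 without NUP98-CDX4 replicates 1 and 2. The remaining 19 lists besides the sex-linked genes did not pass, their camera adjusted p running from 0.076 for the immediate early genes (under 0.05 in 6 of 24 other settings) to 0.98 for the Hoxc and Hoxd genes. Median, mean and test differed in sign for the B cell, T and NK cell, stromal and polycomb lists.

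No named gene of this comparison held its call in every setting tried, and the count of 18 ran from 0 without NUP98-CDX1 replicate 1 (by limma, with 461 genes at an unadjusted p under 0.05) to 30 without NUP98-CDX4 replicate 2. With an estimated correlation 3 of the 11 lists passed, and 0 did with array set as a block as well (adjusted p = 0.16 for the Hoxa, late neutrophil and mast cell lists).

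The changes of both fusions against EGFP were then set side by side to ask what they share. Of the genes called, 109 passed in both comparisons, 63 higher in both and 46 lower in both, and 0 in opposite directions. Independent lists would share 2.00 and 1.68, the product of the calls in each direction over 10018 genes. Across genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.753 and a covariance of 0.17. Both comparisons use the same 3 EGFP arrays. Simulations with no effect gave a mean r of 0.497, at most 0.533, a mean covariance of 0.0381, and at most 1 gene called in both. Their noise was independent between arrays and left out the array sets, so these values can differ from what no effect gives here. Drawn labellings of the real arrays, other than the real one, gave up to 79 genes called in both in the same direction. The covariance beyond the simulated one, 0.132, estimates the shared effect, but 3 control arrays cannot be split into 2 groups of at least 2, so part of the excess may come from the shared controls. With array set as a block 569 genes passed in both, r was 0.839 and the covariance difference 0.162.

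The mean of both fusions against EGFP asks which genes differ on average over the fusions. A large change in 1 fusion can carry such a call. It called 508 genes, 268 higher and 240 lower (5.07%), and 1638 with array set as a block. The genes changed most in both, ranked by the smaller of their changes, were Vldlr, Eya1, Dlk1, Adgrl4 and Hpgd among the rises and Stfa2, Cma2, Mcpt4, Tpsb2 and Cstdc5 among the falls. Of the 508, all had the same direction in both fusions. Selection on the mean of both favours such genes, so this is no separate evidence that the fusions agree. Of these genes 429 (84.4%) changed more in NUP98-CDX4, by a median ratio of 1.36. With array set as a block 1633 of 1638 had the same direction and 1327 (81.0%) changed more in NUP98-CDX4. Of the lists, 13 passed, 7 higher and 6 lower, against 5 with an estimated correlation. The Hoxa median was 1.09 (camera adjusted p = 6.1e-10), the late neutrophil median -1.60 (1.9e-25), the mast cell median -1.23 (6.1e-14) and the interferon median -1.21 (7.8e-27, 0.059 with an estimated correlation). With array set as a block these medians were 1.08, -1.63, -1.29 and -1.27. Without NUP98-CDX4 replicates 1, 2 and 3 the Hoxa median was 1.781, 1.774 and 1.666, with Hoxa3 and Hoxa10 then out of the list. Without EGFP replicate 3 the mast cell median was -0.64. For the erythroid and ribosome lists median, mean and test differed in sign. The count of 508 was 227, 183 and 336 without EGFP replicates 1, 2 and 3, and the block with an estimated correlation called 0 lists.

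**Figure D1:**
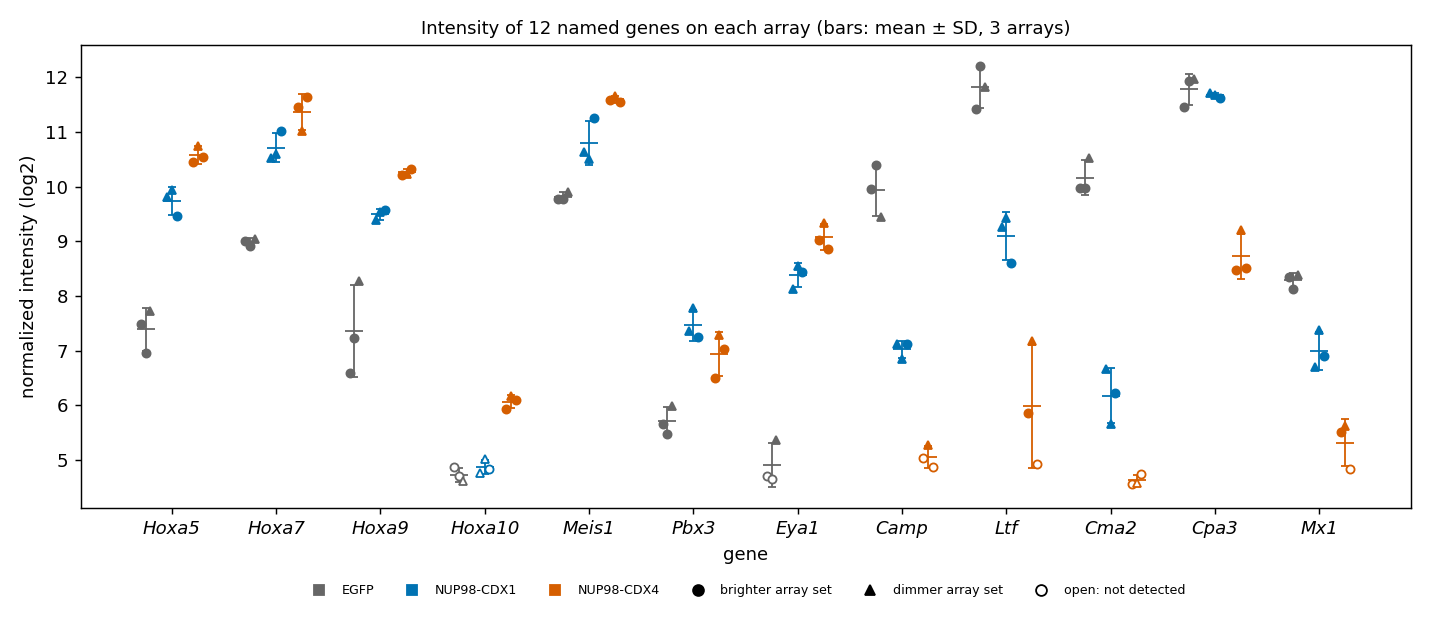
Log2 intensity of 12 genes on each array, by group, with mean ± SD bars (n = 3), circles for the brighter set, triangles for the dimmer set and open symbols for probes not detected. Hoxa5 read 7.39, 9.74 and 10.58 on average in EGFP, NUP98-CDX1 and NUP98-CDX4, and Cpa3 11.79, 11.68 and 8.73.

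**Figure D2:**
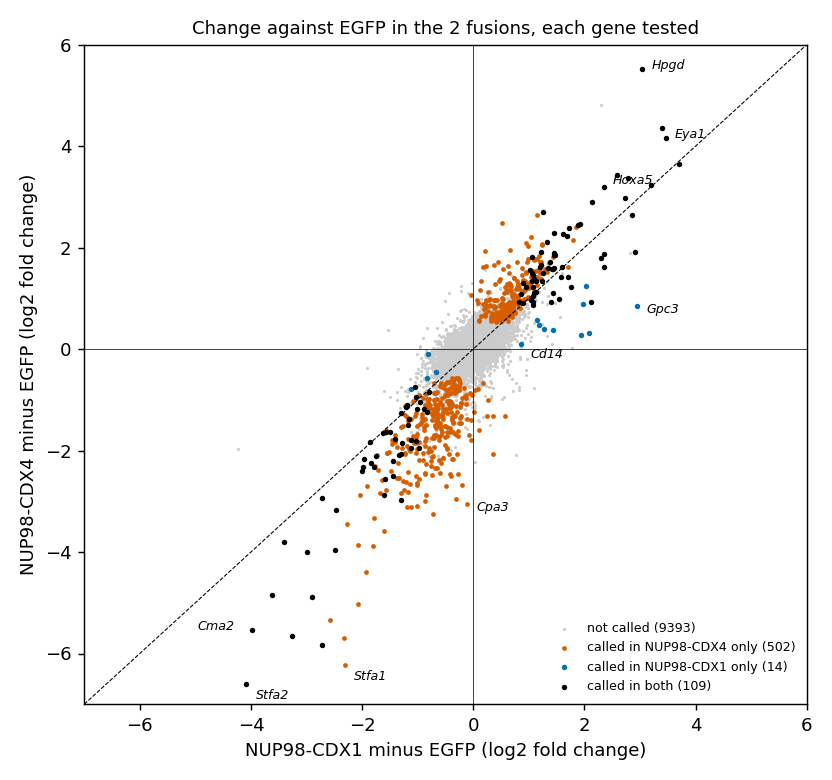
Each point is a gene, with its log2 change against EGFP in NUP98-CDX1 on the horizontal axis and in NUP98-CDX4 on the vertical axis. Colours mark genes called in both fusions (109), in 1 or in none, and the dashed line marks equal change.

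**Figure D3:**
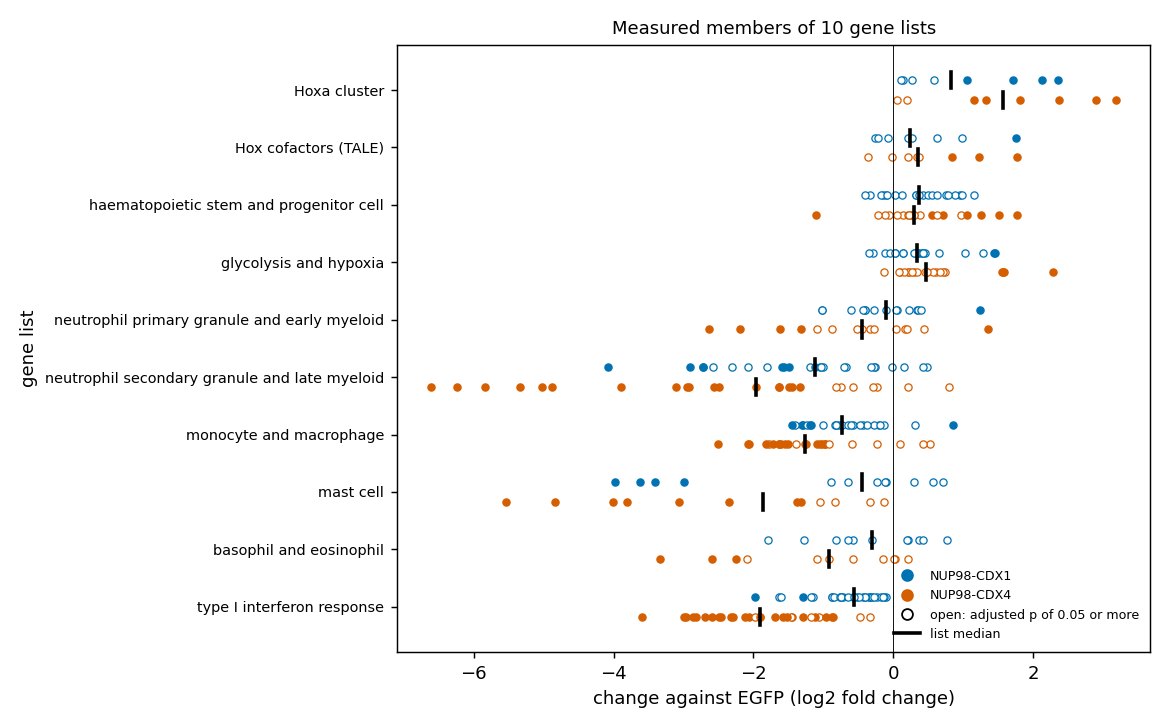
Log2 changes against EGFP of the members of 10 gene lists, NUP98-CDX1 in blue and NUP98-CDX4 in orange. Filled points had an adjusted p under 0.05 and black bars are list medians, such as 0.82 and 1.58 for the Hoxa cluster.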

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

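The tests of array set, day number, single arrays and macrophage share in this part were chosen after the results were seen, and that of sex after the Xist levels were seen but before its own value. The results named first stand out because the difference between the fusions, both set against EGFP, passed a test of its own. By limma 18 genes differed between NUP98-CDX4 and NUP98-CDX1. As log2 differences, Hpgd was higher in NUP98-CDX4 by 2.47, Myadml2 by 1.46 and Clec10a by 1.71 (1.59 with undetected arrays raised to their lowest detected signal). The fitted 1.20 of Hoxa10, undetected in NUP98-CDX1, is no measured size, and it was at least 1.71-fold higher. Stfa1 was lower at -3.93, Cpa3 at -2.95, Stfa2 at -2.53 (-2.15 with undetected arrays raised) and Hsd11b1 at -2.52. The fitted -2.42 of Stx3, undetected in NUP98-CDX4, is no measured size either, and it was at least 4.49-fold lower. The count of 18 was 6 without EGFP replicate 2, 0, 1 and 11 without NUP98-CDX1 replicates 1, 2 and 3, and 2, 30 and 7 without NUP98-CDX4 replicates 1, 2 and 3, the 0 leaving 461 genes at an unadjusted p under 0.05.

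By camera 11 lists differed between the fusions. The medians of NUP98-CDX4 minus NUP98-CDX1 were 0.76 for the Hoxa cluster (0.74 with undetected genes at their bound) and 0.26 for glycolysis and hypoxia. They were -1.24 for mast cell genes (-0.73 at the bounds), -1.11 for the interferon response, -0.84 for late neutrophil genes, -0.63 for macrophage genes and -0.50 for basophil and eosinophil genes. They were -0.45 for megakaryocyte genes, -0.45 for NF-kB genes (-0.37 at the bounds), -0.24 for primary granule genes and -0.09 for the amino acid response. With an estimated correlation 3 of these lists kept an adjusted p under 0.05, Hoxa, late neutrophil and mast cell, each at 0.049, and with array set as a block as well 0 did (0.16 for these 3). Without NUP98-CDX4 replicate 2 the calls of the Hoxa list (adjusted p = 0.083) and the amino acid list (0.451) were lost, the latter also without NUP98-CDX1 replicate 1 (0.197). Hoxa3 and Hoxa10 are out of the Hoxa list without NUP98-CDX4 replicate 2. Without NUP98-CDX4 replicate 3 the NF-kB median was -0.128, the macrophage median -0.384 and the primary granule median -0.151, and without NUP98-CDX1 replicate 1 the NF-kB median was -0.162 and the primary granule median -0.155. The NF-kB median was -0.277 without NUP98-CDX4 replicate 1, and the amino acid median -0.223, -0.177 and -0.044 without NUP98-CDX1 replicate 3 and NUP98-CDX4 replicates 1 and 2. The basophil median was -0.822, -0.822 and -1.131 without EGFP replicates 1, 2 and 3, -0.805 and -0.766 without NUP98-CDX1 replicates 2 and 3, and -1.092 without NUP98-CDX4 replicate 2. Outside the named genes, 14 probes without a gene symbol passed in NUP98-CDX1 and 95 in NUP98-CDX4, and what they measure was not analysed here. Single outlying arrays within a group of 3 were not tested, and array weights ran from 0.282 to 3.44.

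Late neutrophil, macrophage and mast cell genes were lower in both fusions, although in NUP98-CDX1 only 8 of 25, 5 of 25 and 4 of 12 fell singly and the 3 list calls were lost with an estimated correlation (adjusted p = 0.061, 0.13 and 0.13). A difference between the array sets is argued against, since the highest median within either set was -0.798 for the neutrophil and macrophage lists and -0.261 for the mast cell list. The day numbers in the column names were 21 for EGFP, 28 for NUP98-CDX1 and 17 or 20 for NUP98-CDX4, so a change in 1 direction with the day would move the fusions apart. The highest median of either fusion without 1 array was -0.574 for the neutrophil and macrophage lists, which argues against that, and -0.072 for the mast cell list without EGFP replicate 2, which leaves it open there. An effect of the fusions on maturation, and a lower share of mature cells in these cultures for another reason, may both lie behind the pattern and cannot be told apart.

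Of the 508 genes called for the mean of both fusions, 84.4% changed more in NUP98-CDX4. Array set is argued against by a share of 81.0% of the 1638 genes called with array set as a block. Of the 508 genes, 82.3% changed more in NUP98-CDX4 in the brighter and 83.3% in the dimmer set alone. The sex of the cells is argued against by 84.9% of the genes called with array set and Xist as blocks. Without 1 array the share of the genes then called ran from 72.3% to 90.7%, lowest without NUP98-CDX1 replicate 3. The day in the column names cannot be told apart from the fusion, since 0 day numbers are shared by 2 groups. How much of each fusion protein the cells made was not measured, and it may be the reason, as may a stronger fusion.

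The interferon response genes were lower in NUP98-CDX4 than in NUP98-CDX1 as a list by camera, with 2 of 31 passing singly and an adjusted p of 0.076 with an estimated correlation. Array set is argued against by a median of -0.805 in the set where it was higher, and a single array by -0.959, the highest median without 1 array (without NUP98-CDX4 replicate 3, the lowest being -1.44 without NUP98-CDX4 replicate 2). With array set as a block the interferon median was -1.16 and the macrophage median -0.48, a difference of -0.675 (95% bootstrap interval over genes -1.01 to -0.21). A lower share of macrophages as the only source would need genes that only macrophages express to fall as far. Members of the macrophage list that other blood cells share could hold its median up, and the interval measures spread between genes, not arrays. Such a lower share is therefore left open. The day number stays open as a source, and the mast cell, neutrophil and interferon lists may differ between the fusions through it or through the fusions themselves.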

How the results depend on the processing

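Array set as a block, each set alone, and array set and Xist as blocks were chosen after seeing the data. In the order NUP98-CDX1 against EGFP, NUP98-CDX4 against EGFP, NUP98-CDX4 against NUP98-CDX1, mean of both, and genes called in both in the same direction, the counts were 123, 611, 18, 508 and 109. Array weights gave 3816, 1782, 2994, 2588 and 910, and 22 more in opposite directions, with weights of 0.282 to 0.287 for EGFP replicate 3, NUP98-CDX1 replicate 3 and NUP98-CDX4 replicate 2, the single array of the other set in each group. The replicate block gave 31, 371, 1, 261 and 29, though replicates share only a number and same-number pairs correlated at -0.79 to 0.67. Array set as a block gave 619, 1835, 168, 1638 and 569, as the median residual SD fell from 0.272 to 0.157. The brighter array set only gave 50 for NUP98-CDX1, 8 between the fusions and 49 in both. The dimmer array set only gave 4, 108, 0, 71 and 4, by limma with fewer arrays, the 0 leaving 807 genes at an unadjusted p under 0.05. Array set and Xist as blocks gave 538, 1079, 97, 1174 and 449. An adjusted p under 0.01 gave 30, 240, 2 and 200, and at least a 2-fold change 295 for the mean. Between the fusions no filter gave 8 and only the groups compared 3, and the cause was not tested. The correlation of the fusions' changes, 0.753, was 0.536 with array weights, 0.839 with array set as a block and 0.845 with array set and Xist as blocks.

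Without 1 array in turn, the counts ran from 24 to 133, 277 to 638, 0 to 30, 183 to 494 and 22 to 110, and the correlation from 0.601 without NUP98-CDX1 replicate 3 to 0.803. A single array left in a set or group is assumed to vary like the others. NUP98-CDX1 fell to 38, 24 and 74 without EGFP replicates 1, 2 and 3, and to 41 and 32 without NUP98-CDX1 replicates 1 and 2. NUP98-CDX4 fell to 346 and 277 without EGFP replicates 1 and 2, and to 361 and 326 without NUP98-CDX4 replicates 1 and 3. The difference between the fusions gave 6 without EGFP replicate 2, 0, 1 and 11 without NUP98-CDX1 replicates 1, 2 and 3, and 2, 30 and 7 without NUP98-CDX4 replicates 1, 2 and 3, the 0 leaving 461 at an unadjusted p under 0.05. The mean gave 227, 183 and 336 without EGFP replicates 1, 2 and 3. The genes called in both were 35, 22 and 66 without these, and 41, 31 and 71 without NUP98-CDX1 replicates 1, 2 and 3.

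No background correction, an offset of 50, the authors' values, stricter detection, the mean of probes, every probe, and a trended and robust fit kept every total they gave within 1.5 times. Calls in 1 direction moved further. The lower calls in NUP98-CDX1 went from 50 to 76 with the authors' values. Between the fusions they went from 14 to 22 with an offset of 50 and to 23 with stricter detection. Median scaling also kept its totals within 1.5 times. It moved the median difference of all genes between the fusions from 0.007 to 0.107 and the NUP98-CDX1 calls from 73 higher and 50 lower to 56 and 58. Among single genes and lists, 8684 results stayed on their side of the threshold or within their spread, 527 lost and 320 gained a call, and 189 moved. A reversal was counted only for results called before any alternative was applied, and 0 reversed. Lists were judged by the direction of camera and not by their median. In NUP98-CDX1 the calls of the NF-kB, immediate early and cholesterol lists were lost in some settings, in NUP98-CDX4 those of the TALE, leukaemia, amino acid and Wnt lists, and between the fusions those of 6 of 11. Slide as a block was not run, since the files name no slides. Signals near background limit what undetected genes show.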

Other observations

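The tests of mast cell share and of sex-linked levels in this part were chosen after the results were seen, and the counts of other splits of the arrays before, except that with array set as a block, which was chosen once the array sets were seen. The genes of the first paragraphs were chosen after their values were seen. Ccl7, a chemokine that attracts monocytes, fell by 3.12 on the log2 scale in NUP98-CDX4 (adjusted p = 0.00286, detected on 2 of 3 NUP98-CDX4 arrays), Ccl12 by 2.83 (adjusted p = 0.00606, 2 of 3 arrays) and Ccl8 (adjusted p = 0.00214, 1 of 3 arrays) by 2.21 with undetected arrays raised to their lowest detected signal. None of these 3 passed in NUP98-CDX1, nor did their differences between the fusions (adjusted p = 0.133, 0.315 and 0.182), and Ccl3, a chemokine of another group, rose in both fusions. Chil4, a chitinase-like protein of alternatively activated macrophages, fell by 3.86 in NUP98-CDX4 (adjusted p = 0.00149, 2 of 3 arrays), and Fn1, fibronectin, fell in both fusions (adjusted p = 0.0314 and 0.00405), to undetected in NUP98-CDX4. The iron exporter Slc40a1 fell by 2.67 in NUP98-CDX4 (adjusted p = 0.00726, 2 of 3 arrays).

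Among rises outside the lists, Cd27, a receptor of lymphoid-primed progenitors, rose 2.75-fold and 3.01-fold in NUP98-CDX1 and NUP98-CDX4 (adjusted p = 0.0171 and 0.00318). Etv4, a transcription factor, rose 3.26-fold and 2.69-fold (adjusted p = 0.00358 and 0.00267), Tgm2, a transglutaminase, 5.10-fold and 3.06-fold, and Gimap1, a GTPase of lymphocytes, 2.75-fold and 3.64-fold. In NUP98-CDX4 Egfl7, a vascular growth factor that progenitors also make, rose 3.37-fold (adjusted p = 0.00683), and Dach1, undetected in EGFP, at least 2.13-fold (adjusted p = 0.00152). Other probes of Gimap1, Egfl7 and Dach1 did not pass and moved under 0.5 times as far. In NUP98-CDX1 the hepatocyte growth factor gene Hgf rose from 7.56 to 9.53 ± 0.59 (adjusted p = 0.0306, 2 other probes not passing), and did not pass in NUP98-CDX4 (adjusted p = 0.209), nor did the difference between the fusions (adjusted p = 0.373). Of the genes that differed between the fusions and are not described above, Rgcc, Cldn15, Csta3 and Mogat2 were also lower in NUP98-CDX4.

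In NUP98-CDX1 4 mast cell proteases fell while other mast cell genes, the protease Cpa3 among them, did not pass, and a smaller share of mast cells alone would lower all of them by about as much. Of 11 mast cell genes detected on all EGFP arrays, the 4 called had a median of -3.60 with array set as a block and the others -0.20. All 7 others fell short of 0.5 of the called genes' median by over 2 standard errors, but all 7 are shared with basophils or other blood cells. A smaller share of mast cells alone may therefore still lie behind the fall of these 4, and it is not separated from a loss of their expression.

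By the brightest probe of each gene, on 9 of 9 arrays either Xist was high or both Eif2s3y and Kdm5d were detected, and never both, which cells from animals of both sexes would give. A weaker probe of the Y-linked Uty was detected near background on all 3 arrays with high Xist, at 5.283 to 5.502, and a second Eif2s3y probe on 1. The Uty probe was undetected, at 5.015, on NUP98-CDX1 replicate 2, so its detection does not follow that of Eif2s3y and Kdm5d. Within NUP98-CDX1 and NUP98-CDX4 the arrays differed in this, while the 3 EGFP arrays were alike. Xist read 11.33 to 11.87 where it was high and 4.47 to 4.58 elsewhere. This argues against 1 animal as the source of the 3 arrays of either fusion. The labels do not state the animals.

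The 6 arrays of a comparison with EGFP make 10 splits, too few to judge chance. For NUP98-CDX1 against EGFP, 2 of 10 splits called at least the real 123 genes. The highest other split called 1633 and parts EGFP replicates 1 and 2 and NUP98-CDX1 replicate 3 from the rest, which is the array set, and with array set as a block the real count was 619. For NUP98-CDX4 against EGFP 1 of 10 splits, the real one, called 611 genes, and the highest other 0 by limma, with up to 951 at an unadjusted p under 0.05. For NUP98-CDX4 against NUP98-CDX1, 2 of 10 splits called at least 18 genes, the other, 2166, again being the array set, against 168 with array set as a block. Splits that call several times the real count point to a structure of the samples.

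With both fusions as 1 group against EGFP, 4 of 84 splits called at least the real 373 genes. The splits besides the real one, at 1763, 1150 and 871, each hold 3 arrays of the dimmer set. The highest holds NUP98-CDX1 replicates 1 and 2 and NUP98-CDX4 replicate 2. This count follows the array sets, so it cannot exclude chance by itself. With array set as a block 1 of 84 splits, the real one, called 1267 genes. The highest other, the NUP98-CDX4 arrays against the rest, called 273. This argues against a random assignment of the 9 arrays, although the block was chosen once the sets were seen and the splits moved arrays between sets. A chance difference between cultures is not excluded, since the labels do not say whether the replicates were separate cultures. For gene lists chance cannot be excluded, since 13 of 84 splits called at least the real 12 lists, and up to 15. For the overlap of the fusions 1 of 100 drawn labellings, the real one, gave 109 genes and the highest other 79. This argues against a random assignment of the 9 arrays to the groups. It does not test overlap beyond the shared controls, since a shift in the 3 EGFP arrays alone would also give shared calls. Array set was not a block in these fits.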
